A study of Aethionema arabicum with 12 samples.

How the data were processed

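RNA was measured in imbibed seeds of Aethionema arabicum, a small annual of the crucifer family, from a Turkish accession (TUR) and a Cypriot accession (CYP). Seeds were held in darkness or under white light of 100 µmol m-2 s-1 for 23 h, and intact seeds that had not germinated were frozen. Per the labels' protocols, poly(A) RNA from total seed RNA was made into libraries with the Lexogen SENSE mRNA kit, and the 12 libraries (3 per group, 4 groups) were sequenced on an Illumina HiSeq instrument. The submitters' processing notes name bcl2fastq 2.17.1, Trimmomatic, Bowtie2 2.2.3, HTSeq 0.6.1 and TAIR10, without the role of each. The release of the A. arabicum genome behind the gene models, and whether counting used strand, are not given in the sources used here.

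The deposited table holds, per the file headers, a raw count and an RPKM value of every library for 23594 A. arabicum gene models. Each model has a length in bases and, for 21079 models, a matching Arabidopsis thaliana (TAIR10) gene with its description. The deposited RPKM of the CYP libraries equals the count divided by gene length and by the column's total count. The deposited RPKM of the TUR libraries does not. Read back as whole reads, it accounts for 29.8 to 38.4% of the counted TUR reads, and 100% of its values came out whole, within 0.01 reads up to 100 reads and within 0.01% of the value above. What the authors divided to make those values is not given in the sources used here. RPKM of TUR and CYP libraries were therefore not compared with each other, and the deposited counts were used throughout.

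The test fixed before the data were examined was limma on log2(RPKM + 1), since the table was thought to hold RPKM alone, with edgeR named for the case of counts. The counts led to edgeR's quasi-likelihood test as the main test, with the planned test on RPKM computed from the counts as an alternative. Genes with at least 1 CPM (reads scaled to the library total) in at least 3 libraries were tested, which left 15671 of the 18849 models with a count above 0. Libraries were scaled with the TMM method in edgeR 4.0.16 (R 4.3.3), the 4 group means were fitted to all 12 libraries together, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. RPKM computed from the counts used the library total alone, without TMM scaling. A gene was called at an adjusted p under 0.05. The 5 comparisons were light against dark in TUR, light against dark in CYP, the difference between these light responses (CYP minus TUR), and CYP against TUR in darkness and in light. Standard errors (SE) of log2 fold changes come from the same test. Levels are TMM-scaled CPM, given as mean ± SD over the 3 libraries of a group. Adjusted p-values of single genes in the text come from this test unless another tool is named.

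Total counts ran from 7099578 to 13953792 per library, so that 3 counts in 1 library stand for 0.215 to 0.423 CPM. Where a group had 0 reads, a fold is given as a lower bound against 3 counts summed over the group. With 1 to 3 reads it is given as a ratio with its 95% interval. Intervals and floors cover counting error only. On counts simulated from these libraries with 100 genes changed 1.5-fold and 100 changed 2-fold among those of at least 5 CPM, up and down alternately, the test recovered 73% and 96% of them in the TUR light comparison and 64% and 98% in CYP. It recovered 23% and 77% for the difference between accessions, and 65% and 100% between accessions in darkness (71% and 99% in light). False calls were 12 of 181 calls in TUR, 6 of 168 in CYP and 9 of 109 for the difference. Between accessions they were 15 of 180 in darkness and 11 of 181 in light.

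A total of 25 gene lists (402 Arabidopsis loci, of which 314 have a match in the table) were written before the data were examined. They cover light perception and its signalling, the clock, plastid pigments and photosynthesis, flavonoids, hormones, dormancy, seed reserves, cell wall, cell division, ribosomes, stress, and markers of embryo axis, endosperm and seed coat. Lists with at least 5 measured members were tested in the 3 light comparisons with camera in limma 3.58.1 (preset correlation 0.01), adjusted over 63 tests. The same test with an estimated correlation and fry were alternatives. Of the 24 list calls, 13 hold with an estimated correlation. In a simulated list of 16 genes raised 1.5-fold the camera adjusted p was 4.09e-53, and 0 of 100 unchanged lists were called. Genes were drawn independently there and only those 16 changed, so the simulation does not test the preset correlation.

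The genes named in the text were set by a rule fixed before the data were examined. For each light comparison it took the 8 largest rises and 8 largest falls among called genes with a known function and at least 5 RPKM in the higher group, with no overlap of libraries between the groups. For the difference between accessions the condition on overlap was left out. It added up to 4 called members of each list and direction and a set of seed and light regulators whatever their p. For the accession comparisons it took the 5 largest each way. Not every gene that this rule takes in the accession comparisons is reported here. The RPKM limit used values computed from the counts. Gene symbols are those of the matching Arabidopsis genes. In all, 2541 Arabidopsis genes match at least 2 models, and reads of such related models may have been split by the counting, so their values are uncertain. Positions of the genes in the genome were not analysed here.

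Alternatives fixed before the data were examined were median-ratio and quantile scaling, no count filter or a stricter one, a fit without a dispersion trend or with robust shrinkage, only the compared groups in the fit, replicate number as a block, a 2-fold or a stricter threshold, other pseudocounts, DESeq2 1.42.0, and leaving out each library in turn. Chosen after seeing the data were the planned test on RPKM computed from counts, deposited RPKM within each accession, the reads recovered from TUR RPKM, libraries thinned to the smallest total, list counts without CYP dark replicate 3, and gene families by description text. The labels do not say whether the replicates are separate seed batches, so the p-values measure the spread between these samples, which may be technical.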

Results

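Transcripts were counted in imbibed, intact seeds of Aethionema arabicum that had not germinated, from the accessions TUR and CYP, after 23 h in darkness or in white light of 100 µmol m-2 s-1. Light is known to inhibit germination of CYP seeds and not of TUR seeds, and the design allows the light response of each accession and the difference between them to be measured. Each of the 4 groups held 3 libraries. Total counts were 12913162, 10593432 and 12448026 in TUR dark replicates 1 to 3, 12857387, 7757898 and 12916348 in TUR light, 10256583, 8408138 and 7099578 in CYP dark, and 12592460, 11859481 and 13953792 in CYP light. The first principal component of the log2 CPM values held 63.04% of the variance and separated the accessions, and the second held 19.39% and separated light from dark. CYP dark replicate 3 stood apart on the third component (4.51% of the variance), with a score of 37.59. Its correlation with the other CYP dark libraries across genes was 0.9805 and 0.9806, against 0.9902 between those.

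**Figure D1:**
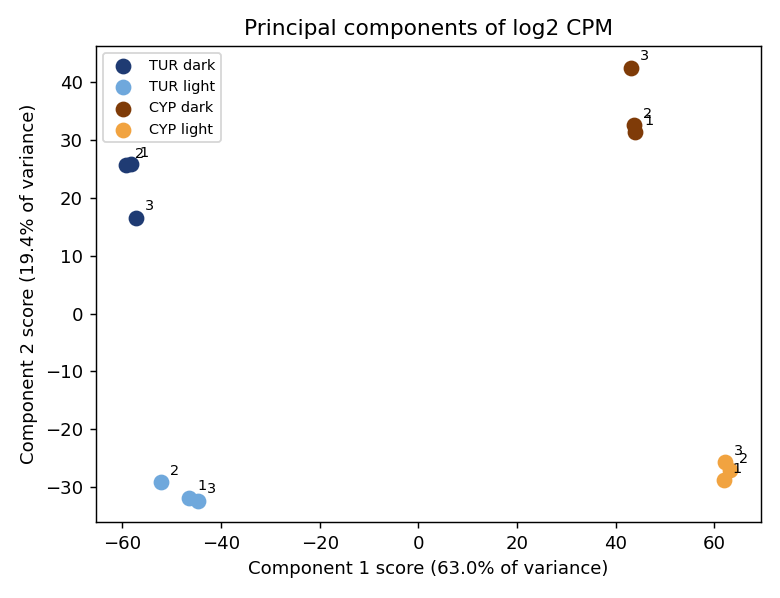
Scores of the 12 libraries on the first and second principal components of log2 CPM, which hold 63.04% and 19.39% of the variance. TUR libraries have negative and CYP libraries positive scores on the first component, and on the second all dark libraries lie above 0 and all light libraries below it.

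In TUR seeds, light raised the genes of flavonoid and anthocyanin synthesis more than any other listed group. Dihydroflavonol 4-reductase (DFR, AA3G00224), which makes the precursors of anthocyanins, rose from 8.69 ± 1.15 to 491 ± 77.2 CPM (SD, n = 3). Chalcone synthase (CHS, AA32G01209), the enzyme that opens the pathway, rose from 25.6 ± 0.152 to 755 ± 54.8 CPM (SD, n = 3). Among the 8 largest rises with a known function were also leucoanthocyanidin dioxygenase (LDOX, AA57G00487), with a log2 fold change of 5.22 (SE 0.13), and the anthocyanin transport protein TT19 (AA40G00386), with 5.37 (SE 0.15). A flavonoid 3-O-glucosyltransferase (AA11G00065) rose by 5.8 (SE 0.16) on the log2 scale, and PYR1-like 11 (AA6G00016), of the abscisic acid (ABA) receptor family, by 6.42 (SE 0.20). A B-box zinc finger gene (AA87G00199) had 2 reads in all dark libraries and 225 in light, a ratio of 119 (95% interval 32.5 to 986). Of 16 flavonoid synthesis genes measured, 14 rose, 0 fell and 2 were not called (14 and 0 adjusted over the list alone), with a camera adjusted p of 2.15e-199, and adjusted p = 3.84e-06 with an estimated correlation. The largest falls were those of an amino acid transporter gene (AA229G00001, log2 fold change -3.92, SE 0.23), an aspartyl protease gene (AA65G00026, -3.52, SE 0.25) and an Integrase-type DNA-binding gene (AA31G00259, -3.35, SE 0.30). Across the 15671 genes tested, 1437 were higher and 1445 lower in light, 2882 in all, of which 593 differed at least 2-fold (340 higher, 253 lower). With limma on log2(RPKM + 1) from the counts 1430 were higher and 1157 lower, and on deposited RPKM 865 and 1079. Without TUR dark replicate 2 the total was 1892 (948 higher, 944 lower), and without TUR light replicate 3 it was 1888, with 875 higher. Without TUR light replicate 1 the rises were 922.

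Regulators of the light response changed in both directions in TUR. HY5 (AA44G00380), a bZIP factor that promotes development in light, rose from 5.96 ± 1.05 to 33.9 ± 6.39 CPM (SD, n = 3), and its homolog HYH (AA26G00433) rose by 3.93 (SE 0.21) on the log2 scale. RUP1 (AA55G00029), a repressor of UV-B signalling, had 1 read in darkness and 109 in light, a ratio of 115 (95% interval 20.2 to 4590). BBX24 (AA114G00006) rose by 3.45 (SE 0.11) and SPA3 (AA15G00087), a partner of the ubiquitin ligase COP1, by 3.34 (SE 0.34). PIL1 (AA21G00425) and ATHB2 (AA53G00281), genes known to be held down by active phytochrome, fell, with log2 fold changes of -2.51 (SE 0.43) and -1.71 (SE 0.17). In the list of 27 light signalling genes, 10 rose, 7 fell and 10 were not called (10 and 7 adjusted over the list alone), with a camera adjusted p of 1.83e-07. The 16 photoreceptor genes had 4 rises, 4 falls and 8 not called (5 and 4 adjusted over the list alone), with a camera adjusted p of 0.727, a median of 0.00 (0.004), a mean of -0.07 and a test pointing down. Phytochrome A (PHYA, AA65G00005) fell from 374 ± 19.5 to 198 ± 17.9 CPM (SD, n = 3) and the blue light receptor PHOT1 (AA16G00083) from 77.0 ± 5.41 to 27.8 ± 1.07 CPM (SD, n = 3), while PHYE (AA57G00083) rose by 0.81 (SE 0.15). PHYB (AA26G00394) fell by 0.40 (SE 0.10), a call lost without TUR dark replicate 2 (-0.36, adjusted p = 0.058) or TUR light replicate 3 (-0.33, adjusted p = 0.0549). Both models matching PIF1, which holds back germination in darkness, were not called (log2 fold change 0.13 for AA102G00037 and -0.07 for AA33G00286, adjusted p = 0.657 and 0.772).

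Clock genes changed in both directions in TUR. PRR9 (AA21G00407) rose by 4.26 (SE 0.34), GIGANTEA (GI, AA39G00470) by 2.3 (SE 0.11) and LUX (AA16G00033) by 2.1 (SE 0.17), while LHY (AA1G00037) fell from 268 ± 30.4 to 87.6 ± 6.52 CPM (SD, n = 3). Of 19 clock genes, 9 rose, 3 fell and 7 were not called (10 and 3 adjusted over the list alone), with a camera adjusted p of 8.53e-07. Of 10 carotenoid synthesis genes, 7 rose, 0 fell and 3 were not called (8 and 0 adjusted over the list alone), with a camera adjusted p of 5.26e-06. Phytoene synthase (PSY, AA40G00385), which commits carbon to carotenoids, rose by 1.85 (SE 0.12) and lycopene cyclase LCYE (AA44G00684) by 0.97 (SE 0.18). The photosynthetic apparatus list had 38 measured genes, of which 11 rose, 2 fell and 25 were not called (12 and 4 adjusted over the list alone). Its camera adjusted p was 0.00511, and adjusted p = 0.146 with an estimated correlation. The antenna gene LHCB1.4 (AA18G00099) rose from 0.878 ± 0.359 to 15.7 ± 0.184 CPM (SD, n = 3), PSBS (AA54G00046), which protects photosystem II, rose by 1.19 (SE 0.11), and PSBP1 (AA32G00637) fell by 0.74 (SE 0.16). For 17 chlorophyll synthesis genes, 4 rose, 2 fell and 11 were not called (4 and 2 adjusted over the list alone), with a camera adjusted p of 0.167. CHLP (AA31G00501) rose by 1.36 (SE 0.12), and protochlorophyllide reductase PORB (AA32G01096) fell by 1.66 (SE 0.17).

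Among hormone genes of TUR, NCED6 (AA78G00012), an ABA synthesis gene of the endosperm, fell from 12.0 ± 1.29 to 2.74 ± 1.41 CPM (SD, n = 3). NCED9 (AA31G00716) of the same step rose by 1.51 (SE 0.22), and CYP707A2 (AA32G00787), which degrades ABA, by 0.95 (SE 0.12). Of 6 ABA biosynthesis genes, 3 rose, 1 fell and 2 were not called (4 and 1 adjusted over the list alone), with a camera adjusted p of 0.466. All 3 ABA catabolism genes were called, 2 up and 1 down (2 and 1 adjusted over the list alone), the fall being that of CYP707A3 model AA6G00060 (-0.50, SE 0.09). Of 17 ABA signalling genes, 4 rose, 0 fell and 13 were not called (4 and 0 adjusted over the list alone), with a camera adjusted p of 0.331, and the cold and ABA response gene KIN2 (AA40G00505) rose by 1.89 (SE 0.32). Among the rises in these ABA lists, ABA1 (AA8G00025), ABA3 (AA37G00095), CYP707A3 model AA57G00196, AHG3 (AA52G00006) and RD29B (AA55G00020) each depended on single libraries. Where their calls were lost, the adjusted p was 0.0543 to 0.234. ABI3 (AA109G00007) and ABI5 (AA60G00170), central factors of ABA response in seeds, were not called (0.12 and 0.19, adjusted p = 0.43 and 0.412). In the gibberellin (GA) biosynthesis list, 2 of 7 genes rose, 1 fell and 4 were not called (2 and 1 adjusted over the list alone), with a camera adjusted p of 0.845, a median of 0.11, a mean of -0.08 and a test pointing up. The rise of GA3ox1 (AA37G00176) lost its call without TUR dark replicate 2 or 3 or any TUR light library (adjusted p = 0.054 to 0.107). That of GA3ox2 (AA31G00895) lost it without TUR dark replicate 2 or TUR light replicate 1 or 3 (0.0661 to 0.0722). GA20ox2 (AA55G00064) fell by 1.55 (SE 0.39). Of 2 GA catabolism genes, 1 rose, 0 fell and 1 was not called (1 and 0 adjusted over the list alone), and GA2ox2 model AA18G00108, which inactivates GA, rose from 0.249 ± 0.0818 to 5.26 ± 0.794 CPM (SD, n = 3). Of 7 GA signalling genes, 1 rose, 3 fell and 3 were not called (1 and 3 adjusted over the list alone), with a camera adjusted p of 0.331, and the DELLA repressor gene RGA (AA53G00639) fell by 0.57 (SE 0.12). The ethylene list of 10 genes had 3 rises, 3 falls and 4 not called (4 and 3 adjusted over the list alone), with a camera adjusted p of 0.822, a median of 0.05, a mean of -0.04 and a test pointing up. EBF2 (AA12G00084), which limits ethylene signalling, rose by 0.76 (SE 0.10), and the ethylene-forming oxidase gene ACO1 (AA33G00241) fell by 1.2 (SE 0.19). None of 5 auxin response genes was called by edgeR (0 and 0 adjusted over the list alone, camera adjusted p = 0.672), with 1 at an unadjusted p under 0.05 and 0 called by DESeq2.

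Of 14 cell wall loosening genes, 0 rose, 7 fell and 7 were not called (0 and 9 adjusted over the list alone), with a camera adjusted p of 5.09e-05. The expansin EXPA2 (AA35G00022), which loosens cell walls, fell from 251 ± 18.0 to 55.0 ± 27.2 CPM (SD, n = 3), and the GA-regulated gene GASA4 (AA40G00565) from 566 ± 76.6 to 266 ± 47.0 CPM (SD, n = 3). Of 18 cell cycle and DNA replication genes, 1 rose, 5 fell and 12 were not called (1 and 7 adjusted over the list alone), with a camera adjusted p of 0.0259, and adjusted p = 0.0925 with an estimated correlation. The replication licensing gene CDC6 (AA32G00731) fell by 0.86 (SE 0.15) and cyclin CYCD1;1 (AA38G00068) by 1.22 (SE 0.18). Of 6 heat and oxidative stress genes, 5 rose, 0 fell and 1 was not called (5 and 0 adjusted over the list alone), with a camera adjusted p of 3.5e-05, and adjusted p = 0.0509 with an estimated correlation. The chaperone gene HSP70 (AA92G00001) rose by 1.65 (SE 0.12). In the dormancy list, 2 of 11 genes rose, 1 fell and 8 were not called (2 and 1 adjusted over the list alone), with a camera adjusted p of 0.52. DOG1 (AA6G00020), a main dormancy gene, rose by 1.4 (SE 0.39), a call lost without TUR dark replicate 2 (0.99, adjusted p = 0.0617) or TUR light replicate 1 (0.99, adjusted p = 0.143), and SPATULA (SPT, AA30G00231) fell by 0.78 (SE 0.18). Seed storage genes had 2 rises, 0 falls and 9 not called of 11 (2 and 0 adjusted over the list alone), with a camera adjusted p of 0.395. The rises of OLEO2 (AA87G00124) and ECP63 (AA60G00129) depended on single libraries, with an adjusted p of 0.0556 to 0.193 where their calls were lost. Of 18 reserve mobilisation genes, 2 rose, 2 fell and 14 were not called (2 and 3 adjusted over the list alone), with a camera adjusted p of 0.52. Isocitrate lyase (ICL, AA26G00814), of the glyoxylate cycle, fell from 8230 ± 561 to 5213 ± 568 CPM (SD, n = 3), a call lost with quantile normalization. Of 14 ribosomal protein genes, 0 rose, 1 fell and 13 were not called (0 and 0 adjusted over the list alone), with a camera adjusted p of 0.331. The 8 embryo axis markers had 0 rises, 1 fall and 7 not called (0 and 1 adjusted over the list alone), with a camera adjusted p of 0.331, the fall being that of the epidermal gene PDF1 (AA21G00071, -1.48, SE 0.20). Of 3 endosperm markers, 0 rose, 1 (NCED6, also counted above) fell and 2 were not called (0 and 1 adjusted over the list alone), with a median of 0.15 (0.145) and a mean of -0.58. Of 3 seed coat markers, 1 rose, 0 fell and 2 were not called (1 and 0 adjusted over the list alone), with a median of -0.16 and a mean of 0.18. TTG2 (AA60G00054), a WRKY factor of the seed coat, rose by 1.00 (SE 0.15).

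**Figure D2:**
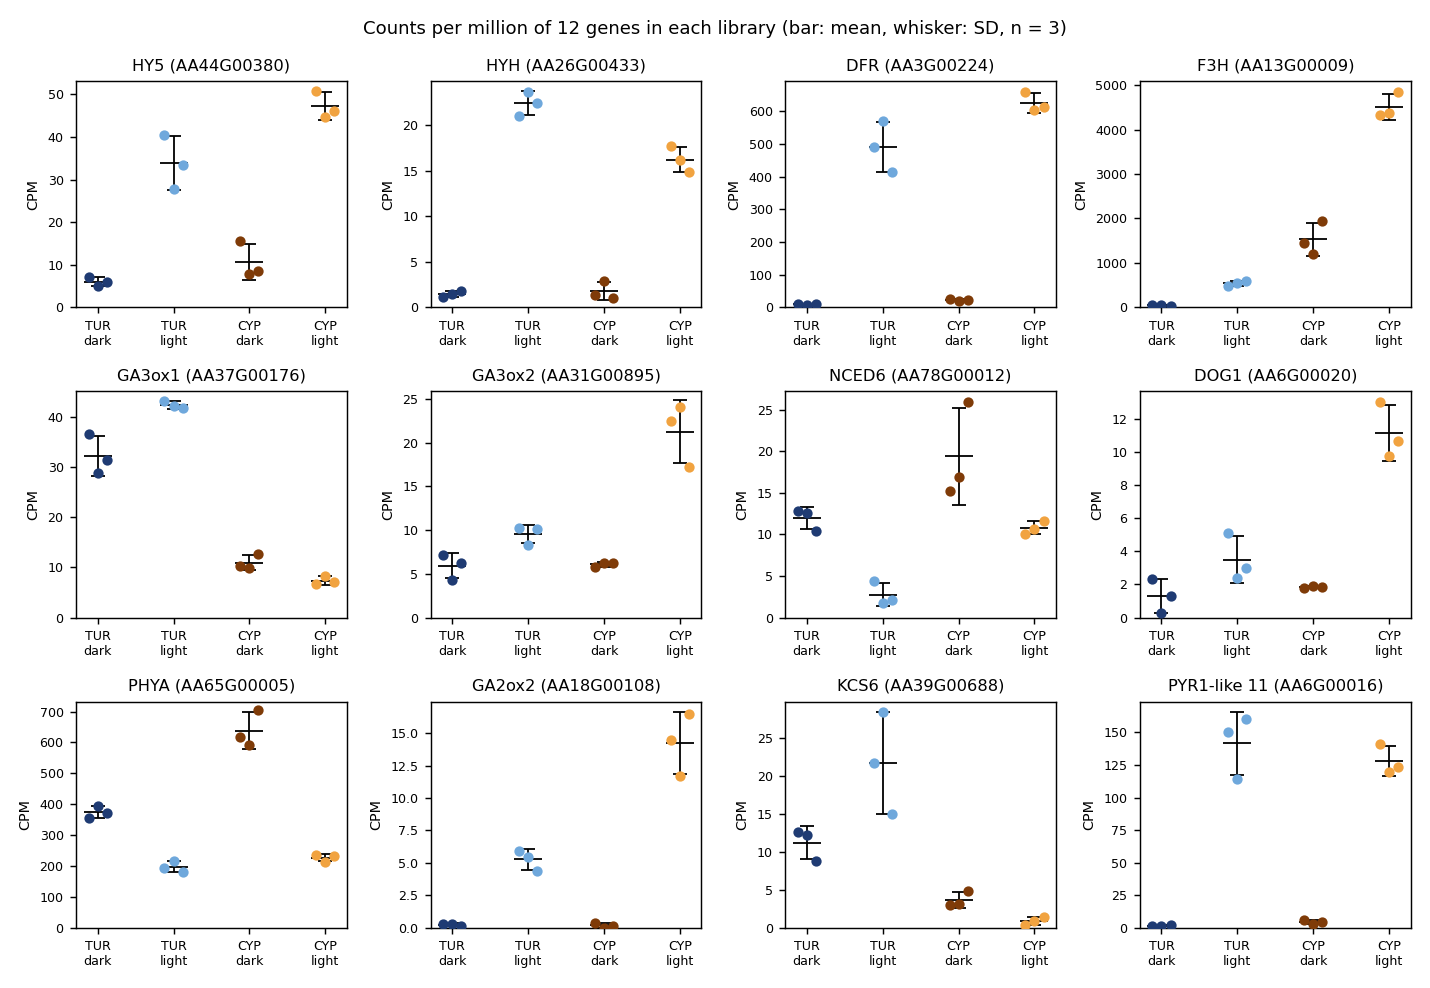
CPM of 12 named genes in each library, by group, with bars for the mean and whiskers for the SD (n = 3). DFR rose from 8.69 to 491 CPM in TUR and from 22.3 to 625 CPM in CYP, and F3H was at 43.1 CPM in TUR dark against 1527 CPM in CYP dark.

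In CYP seeds, light also raised flavonoid synthesis genes. DFR rose from 22.3 ± 2.65 to 625 ± 30.6 CPM (SD, n = 3), CHS from 57.8 ± 10.3 to 1060.3 ± 24.7 CPM (SD, n = 3), and LDOX by 4.37 (SE 0.12) on the log2 scale. Of 16 flavonoid synthesis genes, 14 rose, 0 fell and 2 were not called (14 and 0 adjusted over the list alone), with a camera adjusted p of 1.37e-136, and adjusted p = 1.39e-05 with an estimated correlation. The GA-inactivating GA2ox2 model AA18G00108 rose from 0.184 ± 0.202 to 14.2 ± 2.37 CPM (SD, n = 3), and PYR1-like 11 (AA6G00016) by 4.84 (SE 0.18). A vacuolar iron transporter gene (AA39G00336) had 3 reads in darkness and 250 in light, a ratio of 54.8 (95% interval 18.5 to 268). The largest falls included early nodulin-like protein 8 (AA53G01281, -3.98, SE 0.13), glycosyl hydrolase AA19G00337 (-3.39, SE 0.23) and an extensin-like cell wall gene (AA65G00256), which fell from 928 ± 134 to 110 ± 6.32 CPM (SD, n = 3). The amino acid transporter gene AA229G00001 fell by 3.98 (SE 0.27). In total 3909 genes were called, 1661 higher and 2248 lower in light (57.5% lower), of which 965 differed at least 2-fold. With limma on log2(RPKM + 5) the calls were nearly even, 1790 higher and 1822 lower (50.4%), and on log2(RPKM + 1) they were 1786 and 1886 (51.4%). RPKM was not TMM-scaled there, and the median log2 fold changes were 0.0172 and 0.0294, against -0.0062 in the main test. Without CYP dark replicate 3, the library that stood apart, 3631 were called.

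Light signalling and clock genes changed in CYP as follows. HY5 rose from 10.6 ± 4.25 to 47.3 ± 3.21 CPM (SD, n = 3), HYH by 3.16 (SE 0.23) and SPA3 by 3.69 (SE 0.46). RUP1 had 0 reads in darkness and 93 in light and was at least 20.4-fold higher. ATHB2 fell by 2.54 (SE 0.17) and PIL1 by 3.01 (SE 0.36). In the list of 27 light signalling genes, 10 rose, 6 fell and 11 were not called (11 and 6 adjusted over the list alone), with a camera adjusted p of 5.06e-05, and without CYP dark replicate 3 the falls were 4. Of 16 photoreceptor genes, 5 rose, 4 fell and 7 were not called (5 and 4 adjusted over the list alone), with a camera adjusted p of 0.885. PHYA fell from 638 ± 60.2 to 227 ± 12.1 CPM (SD, n = 3), and PHYB by 0.81 (SE 0.11). Of 19 clock genes, 10 rose, 2 fell and 7 were not called (11 and 2 adjusted over the list alone), with a camera adjusted p of 1.16e-06. PRR9 rose by 5.28 (SE 0.36) and GI by 2.11 (SE 0.11), and CCA1 (AA21G00411), a morning clock gene, fell by 1.25 (SE 0.14). Of 10 carotenoid synthesis genes, 6 rose, 1 fell and 3 were not called (6 and 1 adjusted over the list alone), with a camera adjusted p of 0.000119, and without CYP dark replicate 3 there were 5 rises and 0 falls. PSY rose by 1.82 (SE 0.11) and the carotene hydroxylase gene CHYB2 (AA77G00002) by 1.25 (SE 0.16). Of 38 photosynthetic apparatus genes, 10 rose, 3 fell and 25 were not called (11 and 5 adjusted over the list alone), with a camera adjusted p of 0.15, and LHCB1.4 rose by 3.58 (SE 0.29). Of 17 chlorophyll synthesis genes, 3 rose, 1 fell and 13 were not called (3 and 1 adjusted over the list alone), with a camera adjusted p of 0.269, and without CYP dark replicate 3 the rises were 5. CHLP rose by 1.06 (SE 0.11).

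In the hormone lists of CYP, NCED6 fell from 19.4 ± 5.78 to 10.8 ± 0.773 CPM (SD, n = 3) and CYP707A2 rose by 1.33 (SE 0.12). Of 6 ABA biosynthesis genes, 3 rose, 1 fell and 2 were not called (3 and 1 adjusted over the list alone), with a camera adjusted p of 0.279, and without CYP dark replicate 3 the falls were 2. Of 3 ABA catabolism genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone). Of 17 ABA signalling genes, 7 rose, 1 fell and 9 were not called (8 and 1 adjusted over the list alone), with a camera adjusted p of 0.00968, and adjusted p = 0.105 with an estimated correlation. RD29B (AA55G00020), a desiccation response gene, rose from 273 ± 21.9 to 640 ± 9.35 CPM (SD, n = 3), KIN2 by 3.91 (SE 0.50), and ABI4 (AA29G00257), an ABA response factor, fell by 0.81 (SE 0.14). Of 7 GA biosynthesis genes, 2 rose, 3 fell and 2 were not called (3 and 3 adjusted over the list alone), with a camera adjusted p of 0.955, a median of -0.33, a mean of 0.01 and a test pointing up. GA3ox2 (AA31G00895), which makes active GA, rose from 6.08 ± 0.251 to 21.3 ± 3.59 CPM (SD, n = 3). GA3ox1 (AA37G00176), of the same step, fell by 0.55 (SE 0.15), a call lost without CYP light replicate 1 (-0.475, adjusted p = 0.0516). Of 2 GA catabolism genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone), the fall being that of GA2ox2 model AA54G00411 (-1.77, SE 0.18). Of 7 GA signalling genes, 1 rose, 2 fell and 4 were not called (1 and 2 adjusted over the list alone), with a camera adjusted p of 0.318, and the DELLA gene GAI (AA14G00090) fell by 1.1 (SE 0.17). Of 10 ethylene genes, 1 rose, 1 fell and 8 were not called (1 and 0 adjusted over the list alone), with a camera adjusted p of 0.991, a median of -0.06, a mean of -0.15 (-0.147) and a test pointing up. Of 5 auxin response genes, 2 rose, 2 fell and 1 was not called (2 and 2 adjusted over the list alone), with a camera adjusted p of 0.955, and without CYP dark replicate 3 there were 0 rises and 1 fall. The calls of IAA2 (AA17G00100), IAA3 (AA19G00125), ARF10 (AA32G00876) and ARF16 (AA102G00149) each depended on single libraries. Where they were lost, the adjusted p was 0.0508 to 0.139.

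In CYP light, of 14 cell wall loosening genes, 0 rose, 9 fell and 5 were not called (0 and 11 adjusted over the list alone), with a camera adjusted p of 9.98e-08, and EXPA2 fell from 84.5 ± 7.31 to 10.2 ± 0.828 CPM (SD, n = 3) and GASA4 by 1.95 (SE 0.17). Of 18 cell cycle and DNA replication genes, 2 rose, 10 fell and 6 were not called (2 and 10 adjusted over the list alone), with a camera adjusted p of 0.000119. The replicative helicase gene MCM5 (AA224G00011) fell from 80.1 ± 2.60 to 36.6 ± 2.91 CPM (SD, n = 3), and the origin recognition gene ORC1A (AA6G00295) fell too, with a log2 fold change of -1.17 (SE 0.18). Of 8 embryo axis markers, 0 rose, 4 fell and 4 were not called (0 and 5 adjusted over the list alone), with a camera adjusted p of 0.0107, and adjusted p = 0.223 with an estimated correlation. PDF1 fell by 2.66 (SE 0.21) and the root patterning gene SHR (AA30G00276) by 1.47 (SE 0.33). Of 11 seed storage and maturation genes, 4 rose, 0 fell and 7 were not called (4 and 0 adjusted over the list alone), with a camera adjusted p of 0.0073, and adjusted p = 0.492 with an estimated correlation. The oil body gene OLEO1 (AA131G00012) rose from 1311 ± 259 to 2318 ± 99.5 CPM (SD, n = 3), and the late embryogenesis gene ECP63 (AA60G00129) by 1.32 (SE 0.13). Of 6 heat and oxidative stress genes, 4 rose, 0 fell and 2 were not called (4 and 0 adjusted over the list alone), with a camera adjusted p of 0.0124, and adjusted p = 0.209 with an estimated correlation. The rises of HSP101 (AA31G00517), HSFA2 (AA32G01052) and HSP90.1 (AA77G00005) depended on single libraries. Where their calls were lost, the adjusted p was 0.0504 to 0.118. Of 11 dormancy genes, 3 rose, 3 fell and 5 were not called (4 and 3 adjusted over the list alone), with a camera adjusted p of 0.672, a median of -0.01, a mean of 0.14 and a test pointing up. DOG1 rose from 1.85 ± 0.0613 to 11.2 ± 1.70 CPM (SD, n = 3) and SPT fell by 1.92 (SE 0.25). The calls of MFT (AA39G00114) and DAG2 (AA21G00391) depended on single libraries, with an adjusted p of 0.0552 to 0.273 where they were lost. Of 18 reserve mobilisation genes, 1 rose, 4 fell and 13 were not called (1 and 4 adjusted over the list alone), with a camera adjusted p of 0.935, a median of 0.03, a mean of -0.04 and a test pointing down. Of 14 ribosomal protein genes, 1 rose, 2 fell and 11 were not called (1 and 2 adjusted over the list alone), with a camera adjusted p of 0.624. The rise of RPL24B (AA531G00001) and the falls of RPL28A (AA33G00250) and RPL4A model AA93G00120 depended on single libraries. Where these calls were lost, the adjusted p was 0.0618 to 0.166. Of 3 endosperm markers, 1 rose, 1 (NCED6, also counted above) fell and 1 was not called (1 and 1 adjusted over the list alone), with a median of 0.13 (0.125) and a mean of -0.03. Of 3 seed coat markers, 1 rose, 1 fell and 1 was not called (1 and 1 adjusted over the list alone), the rise being that of TTG2 (1.56, SE 0.16) and the fall that of the mucilage gene MUM4 (AA15G00120, -0.94, SE 0.17). Further list genes of CYP also lost their calls without single libraries, with an adjusted p of 0.0509 to 0.154. They were EM6, OLEO3, LCYE, CHYB1, GID1A, ACO1, ACO3, PHOT1 model AA16G00084, LHCB3, FHL, RNR2A and CYCB1;1.

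**Figure D3:**
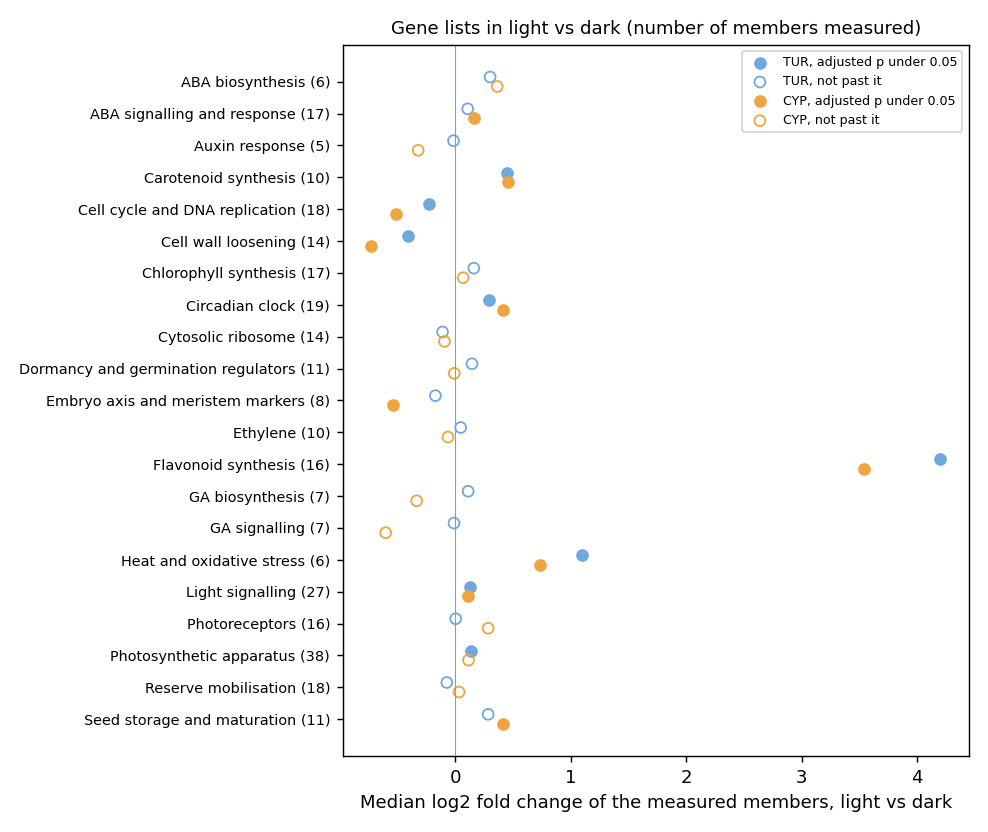
Median log2 fold change of light against dark of the 21 tested gene lists in TUR and in CYP, with filled symbols where the camera adjusted p was under 0.05. The flavonoid synthesis list has the highest median in both accessions, 4.2 in TUR and 3.54 in CYP.

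The light responses of the accessions overlapped by more than independent lists would. Called up in both were 839 genes, against 152.3 for independent lists, and called down in both were 937, against 207.3 (hypergeometric log10 p of -514 and -493.2). Of the 1792 genes called in both, 1776 (99.11%) had the same direction. The log2 fold changes had a Pearson r of 0.677 and a Spearman rho of 0.603 across genes, which are not independent replicates, and these comparisons share no library. Of the genes that fell in both, 700 (74.7%) had the larger fall in CYP, and of those that rose in both 395 (47.1%) had the larger rise in CYP. The 16 genes of opposite direction, chosen after their values were seen, included the wax synthesis genes KCS6 (AA39G00688, 0.93 in TUR and -1.94 in CYP) and KCS10 (AA32G01045, 0.41 and -1.21).

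**Figure D4:**
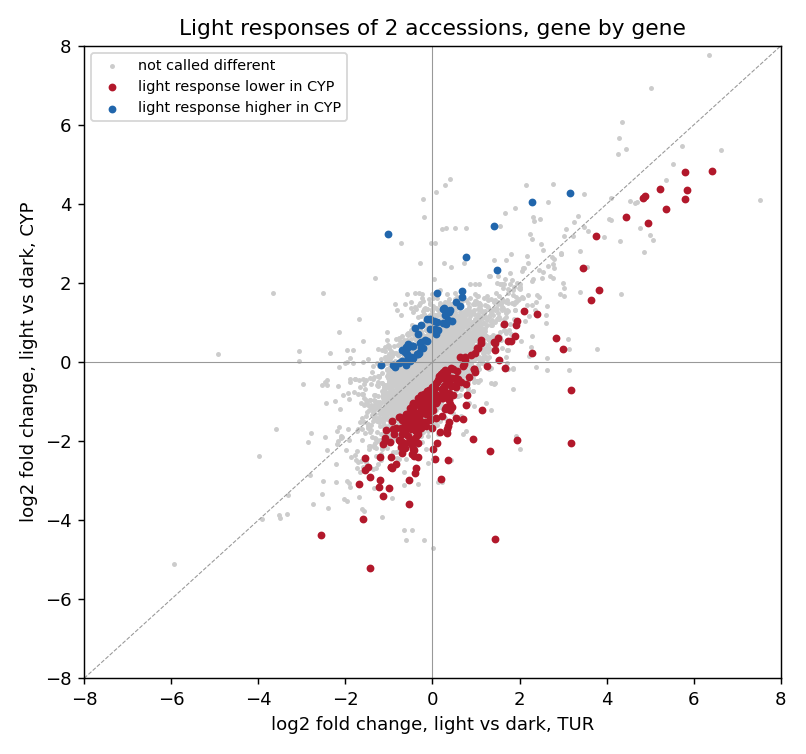
Log2 fold change of light against dark of each tested gene in TUR (x axis) and in CYP (y axis), with genes of a lower response in CYP in red and of a higher response in blue. The 287 lower genes have a median of -1.1 in CYP and -0.09 in TUR, and the 64 higher genes 0.71 and -0.23.

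The difference between the light responses, CYP minus TUR, was called for 351 genes, 64 above and 287 below 0, of which 174 differed at least 2-fold. For 6 of 16 flavonoid synthesis genes the response on the log2 scale was lower in CYP. F3H (AA13G00009), an early enzyme of the pathway, went from 43.1 ± 8.99 to 536 ± 50.7 CPM in TUR and from 1527 ± 370 to 4519 ± 291 CPM in CYP (SD, n = 3), a difference of -2.07 (SE 0.22). TT19 differed by -1.49 (-1.485, SE 0.20), DFR by -1.01 (SE 0.19) and BBX24 by -1.07 (SE 0.15). Of these 16 genes, 0 had a higher response, and 10 were not called (1 and 10 adjusted over the list alone), with a camera adjusted p of 2.44e-08, and adjusted p = 0.034 with an estimated correlation. Without CYP dark replicate 3, 1 was higher and 6 lower. A lower response was not a lower level in F3H, TT19 and DFR, which were higher in CYP than in TUR in both conditions. TT19 was at 19.0 and 283 CPM in CYP dark and light, against 3.53 and 146 CPM in TUR. MCM2 (AA44G00552), a subunit of the replicative helicase, went from 136 ± 7.86 to 114 ± 6.76 CPM in TUR and from 99.2 ± 9.32 to 47.3 ± 4.89 CPM in CYP (SD, n = 3), a difference of -0.81 (SE 0.14). MCM7 (AA32G00239) and MCM5 differed by -0.75 (SE 0.15) and -0.65 (SE 0.13), calls lost without CYP light replicate 1 (-0.67 and -0.58, adjusted p = 0.0566 and 0.06). Of 18 cell cycle and DNA replication genes, 0 were higher, 3 lower and 15 not called (1 and 8 adjusted over the list alone), with a camera adjusted p of 0.00467. An AUX/IAA gene of auxin response (AA32G00414) had a lower response in CYP, with 3 reads in CYP light against 321 in TUR light. Among the next largest differences were those of KCS6 (AA39G00688, -2.87, SE 0.47), proline-rich protein 4 (AA20G00061, -2.85, SE 0.40) and, above 0, an Integrase-type DNA-binding gene (AA31G00404, 1.90, SE 0.34). The count depended on single libraries. It was 195 without TUR dark replicate 2, 196 without replicate 3, 221 without TUR light replicate 1 and 198 without replicate 2. It was 164, 179 and 219 without CYP light replicates 1, 2 and 3. Without CYP dark replicate 3, the library that stood apart, it was 451. The calls above 0 were 41, 32 and 37 without TUR dark replicates 1 to 3 and 40 without TUR light replicate 2. They were 35, 26 and 38 without CYP light replicates 1 to 3, and 112 without CYP dark replicate 3. The calls below 0 were 163 and 159 without TUR dark replicates 2 and 3, 153 and 158 without TUR light replicates 1 and 2, and 129, 153 and 181 without CYP light replicates 1 to 3.

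GA2ox2 model AA54G00411 had a response lower in CYP by 1.95 (-1.946, SE 0.34). The other GA2ox2 model, AA18G00108, had a difference of 1.73 (SE 0.84, adjusted p = 0.382), and values of related models are uncertain. The germination regulator BME3 (AA216G00002) differed by -0.89 (SE 0.16). GA3ox1 went from 32.3 ± 3.95 to 42.4 ± 0.810 CPM in TUR and from 10.9 ± 1.5 to 7.39 ± 0.831 CPM in CYP (SD, n = 3), a difference of -0.94 (SE 0.18) that lost its call without CYP light replicate 1 (-0.84, adjusted p = 0.052). RD29B responded more in CYP, by 0.92 (SE 0.14), and so did ECP63, by 0.91 (SE 0.18). Of 7 GA biosynthesis genes, 1 was higher, 2 lower and 4 not called (1 and 2 adjusted over the list alone), with a camera adjusted p of 0.885, and without CYP dark replicate 3 the lower genes were 1. Of 2 GA catabolism genes, 0 were higher, 1 lower and 1 not called (0 and 1 adjusted over the list alone). Of 14 cell wall loosening genes, 0 were higher, 2 lower and 12 not called (0 and 3 adjusted over the list alone), with a camera adjusted p of 0.00609, and adjusted p = 0.0905 with an estimated correlation. Without CYP dark replicate 3 the lower genes of that list were 3. EXPA9 (AA19G00314) differed by -0.80 (SE 0.14). Of 17 ABA signalling genes, 2 were higher, 0 lower and 15 not called (4 and 1 adjusted over the list alone), with a camera adjusted p of 0.0107, and adjusted p = 0.105 with an estimated correlation. Of 11 seed storage genes, 1 was higher, 0 lower and 10 not called (2 and 0 adjusted over the list alone), with a camera adjusted p of 0.00834, and adjusted p = 0.492 with an estimated correlation. Of 8 embryo axis markers, 0 were higher, 1 lower and 7 not called (0 and 1 adjusted over the list alone), with a camera adjusted p of 0.0233, and adjusted p = 0.283 with an estimated correlation.

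The remaining lists were not called for the difference. Dormancy genes had 1 higher, 1 lower and 9 not called of 11 (1 and 3 adjusted over the list alone, camera adjusted p = 0.731), and without CYP dark replicate 3 the lower genes were 2. Photoreceptors had 0 higher, 1 lower and 15 not called of 16 (1 and 1 adjusted over the list alone, camera adjusted p = 0.35). Light signalling genes had 0 higher, 1 lower and 26 not called of 27 (1 and 2 adjusted over the list alone, camera adjusted p = 0.955). Reserve mobilisation genes had 1 higher, 0 lower and 17 not called of 18 (1 and 0 adjusted over the list alone, camera adjusted p = 0.454), with a median of -0.002, a mean of 0.04 and a test pointing up. Heat and oxidative stress genes had 0 higher, 1 lower and 5 not called of 6 (0 and 1 adjusted over the list alone, camera adjusted p = 0.11). The other 12 lists, with 134 distinct genes, had 0 called by edgeR, with 25 at an unadjusted p under 0.05 and 1, NCED6, called by DESeq2. They were those of ABA biosynthesis, ABA catabolism, GA signalling, the clock, the photosynthetic apparatus, chlorophyll synthesis, carotenoid synthesis, ribosomal proteins, ethylene, auxin response, endosperm and seed coat. NCED6 belongs to the ABA biosynthesis and the endosperm list. Adjusted over the list alone, NCED6 was higher in both of its lists, 1 GA signalling gene was higher and 1 ABA catabolism gene lower, and chlorophyll synthesis and the seed coat list each had 1 higher and 1 lower. Without CYP dark replicate 3, 2 genes were called, both higher, NCED6 and 1 ribosomal gene. The ribosomal list had a median of -0.01, a mean of 0.11 and a test pointing up, and the auxin list -0.20, 0.01 and up. NCED6 differed by 1.24 (SE 0.34, adjusted p = 0.0656) and was called without TUR light replicate 1 (1.81, adjusted p = 0.00926) or CYP dark replicate 3 (1.49, adjusted p = 0.00436). DOG1 differed by 1.19 (SE 0.55, adjusted p = 0.354), HY5 by -0.38 (SE 0.29, adjusted p = 0.609) and MFT (AA39G00114), a regulator of ABA and GA response in seeds, by 0.48 (SE 0.29, adjusted p = 0.504).

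Between the accessions in darkness, a Ribonuclease H-like gene (AA65G00120) was at least 269-fold and an ankyrin repeat gene (AA554G00006) at least 165-fold higher in CYP, with 0 reads in TUR. Summed with other models of the same Arabidopsis match, means over 6 libraries were 288 CPM in TUR and 329 in CYP for the first and 172 and 171 CPM for the second. The 2 genes themselves held 20.36 and 15.05 CPM of the CYP sums, so the sums decide nothing about reads taken by related models. Histone deacetylase 8 (AA214G00007) had 1 read in TUR and a ratio of 993 (95% interval 178 to 39300). Glycosyl hydrolase 9A4 (AA24G00024) was at 0.114 ± 0.0643 CPM in TUR and 59.5 ± 2.86 CPM in CYP (SD, n = 3). In the other direction, a late embryogenesis abundant gene (AA11G00025) was at least 25.7-fold lower in CYP, and a LOB domain gene (AA31G00681) was at 13.3 ± 3.52 CPM in TUR and 0.208 ± 0.0925 CPM in CYP (SD, n = 3). In darkness 6967 of 15671 genes were called, 3509 higher and 3458 lower in CYP (49.6% lower). Those of at least 2-fold were 2057, 825 higher and 1232 lower (59.9%), and limma on log2(RPKM + 1) gave 2749 higher and 3872 lower (58.5%). RPKM was not TMM-scaled there, and the median log2 fold change was -0.0616, against 0.0013 in the main test. Many of these genes share their Arabidopsis match with another model, and their values are uncertain where reads of such models were split. The sequences of the accessions were not analysed here.

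Between the accessions in light, the F-box gene AA31G00313 was at least 122-fold and a cysteine-rich receptor kinase gene (AA361G00006) at least 44.1-fold higher in CYP. Summed with other models of its Arabidopsis match, AA31G00313 was at 91.7 CPM in TUR and 136 CPM in CYP (means over 6 libraries). The gene itself held 12.42 CPM of the CYP sum, which therefore decides nothing about reads taken by related models. The AUX/IAA gene AA32G00414 had 3 reads in CYP and 321 in TUR, a ratio of 117 (95% interval 39.8 to 572). A GDSL lipase gene (AA56G00085) was lower in CYP by a ratio of 60.8 (95% interval 16.5 to 509). In light 8265 genes were called, 3906 higher and 4359 lower in CYP (52.7% lower). Those of at least 2-fold were 2592, 924 higher and 1668 lower (64.4%), and limma on log2(RPKM + 1) gave 3198 higher and 4565 lower (58.8%). RPKM was not TMM-scaled there, and the median log2 fold change was -0.0643, against -0.0215 in the main test. The balance turned with quantile normalization (4171 higher, 4052 lower) and without TUR light replicate 1 (3711 and 3697). The 43 genes of at least 10 CPM in TUR and over 16-fold lower in CYP read at 2.02 to 6.07% of their TUR level in CYP, with a median of 4.23%. With the 40 to 44 genes chosen from the other CYP libraries, that share had a median of 2.93, 2.89 and 6.31% in CYP dark replicates 1 to 3, and of 4.48, 4.09 and 4.71% in CYP light.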

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

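The tests of library depth, of CYP dark replicate 3 and of scaling described here were chosen only after the result was seen, while the splits of the libraries were fixed before. Each result here stands out because the light response differed between CYP and TUR by a test of that difference. Values are CYP minus TUR on the log2 scale, and 351 genes passed in all. Calls of single genes with 1 library left out were followed only for the genes named by the rule. Among those of known function, calls that held with any single library left out were those of the Integrase-type DNA-binding gene AA31G00404 (1.90), homocysteine S-methyltransferase 3 (AA17G00074, 1.2), a RING/U-box gene (AA19G00411, 1.11), RD29B (0.92) and ECP63 (0.91) above 0. Below 0 they were those of F3H (-2.07), TT19 (-1.49), DFR (-1.01), LDOX (-0.84), BBX24 (-1.07), GA2ox2 model AA54G00411 (-1.95), EXPA9 (-0.80), BME3 (-0.89) and MCM2 (-0.81). To these belong KCS6 (AA39G00688, -2.87), proline-rich protein 4 (AA20G00061, -2.85), early nodulin-like protein 8 (AA53G01281, -2.38), glycosyl hydrolase AA19G00337 (-2.25) and a bZIP gene (AA61G00245, -2.21). KCS6 had 35 reads in CYP light and AA61G00245 had 53. The median share of genes over 16-fold lower in CYP light, 4.25% of the TUR level, would give 35 and 46.7. The size of these 2 differences is therefore uncertain while TUR RNA in CYP libraries stays open. The AUX/IAA gene AA32G00414 (-5.23) had 3 reads in CYP light, so that its fitted value depends on the prior count. The lists that differed were flavonoid synthesis (camera adjusted p = 2.44e-08), cell cycle and DNA replication (0.00467), cell wall loosening (0.00609), seed storage (0.00834), ABA signalling (0.0107) and embryo axis (0.0233). Of these, only flavonoid synthesis and cell cycle kept their call with an estimated correlation, with an adjusted p of 0.034 and 0.0365.

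Other calls were lost when single libraries were left out. Without CYP light replicate 1 this held for GA3ox1 (-0.94, then adjusted p = 0.052), MCM7 (-0.75, then 0.0566) and MCM5 (-0.65, then 0.06). A protein binding gene (AA21G00283, -2.42) lost its call without CYP light 1 or 3 or TUR light 1 (adjusted p = 0.0508 to 0.067). Aldehyde dehydrogenase 11A3 (AA22G00103, 1.15) lost it without CYP light 1 or 3, TUR dark 2 or TUR light 3 (0.0543 to 0.0747). For GA3ox2 (1.12) the libraries were CYP dark 1 and 2, CYP light 1 and 2, TUR dark 1 and 3 and TUR light 2 (0.0528 to 0.0827). EM1 (AA215G00006, 0.74) depended on CYP dark 1, CYP light 1 and 2, all TUR dark libraries and TUR light 2 (0.0532 to 0.0981). A receptor kinase gene (AA22G00065, -2.50) depended on CYP dark 2, CYP light 1 and 2, TUR dark 2 and 3 and TUR light 1 and 2 (0.0522 to 0.0996). DOGL4 (AA57G00147, 0.96) depended on CYP light 1 and 2, all TUR dark libraries and TUR light 1 and 2 (0.0618 to 0.0964). LACS7 (AA40G00101, 0.56) depended on CYP dark 2, CYP light 2 and 3, TUR dark 2 and 3 and TUR light 2 and 3 (0.0546 to 0.0667). A gene described by the pectin methylesterase inhibitor family (AA41G00019, 1.11) depended on CYP dark 1 and 2, CYP light 2 and 3, TUR dark 1 and 3 and TUR light 2 and 3 (0.0547 to 0.0766). AA61G00251 (BET1P/SFT1P-like 14A, 1.27) depended on CYP dark 1 and 2, CYP light 2 and 3, TUR dark 1 and 2 and TUR light 1 and 2 (0.0544 to 0.0893). PDF1 (-1.17) depended on all CYP light and TUR light libraries and TUR dark 2 and 3 (0.0747 to 0.113). A bHLH gene (AA21G00569, 1.12) depended on CYP dark 1 and 2, CYP light 1 and 2, all TUR dark libraries and TUR light 1 and 3 (0.0532 to 0.112). CHS (-0.69, 0.0542 to 0.0965), PHYA (-0.57, 0.0509 to 0.14) and HSP70 (AA92G00001, -0.68, 0.0553 to 0.157) depended on CYP dark 1 and on every CYP light and TUR library. EXPA15 (AA53G00740, -0.73, 0.0531 to 0.158) depended on CYP dark 1 and 2, CYP light 1 and 2 and every TUR library. GA20ox1 (AA1024G00001, -0.68, 0.0546 to 0.144) depended on each library but CYP dark 1.

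Of the 351 genes, 287 had the lower response in CYP. After thinning all libraries to the smallest total, at least 72.3% of calls were below 0 in each of 5 thinnings, without CYP dark replicate 3 the share was 75.2%, and with quantile or median-ratio scaling at least 73.1%, which argues against depth, that library and scaling as the whole cause. The share was lower without TUR light replicate 1 (69.2%) and with limma on log2(RPKM + 5) (63.9%). Of the 287, 140 fell in CYP and were not called in TUR, 76 fell in both and 13 rose in TUR and fell in CYP. A further 29 rose in TUR and were not called in CYP, and 29 rose in both. The medians of the 287 were -1.1 in CYP and -0.09 in TUR. A biological difference between the accessions stays open and was not tested, and any part of TUR RNA in CYP libraries was not tested for this pattern.

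For the comparisons of 6 libraries, 10 splits are too few for a share under 0.05, and the real split was the 1 with as many calls each time, with 0 calls as the highest of the other splits. The real values were 2882 in TUR, 3909 in CYP, 6967 between accessions in darkness and 8265 in light. For the difference, 7 of 100 splits, the real split included, called as many genes as the real 351, so chance cannot be excluded on this count. The highest other split called 5432, which points to a structure of the samples. The 6 other splits as large all exchanged light and dark in 1 accession on balance, which turns the shared light response into a difference, and the highest split without such an exchange called 155.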

How the results depend on the processing

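Chosen only after the results were seen were the tests on RPKM computed from the counts at a pseudocount of 1, on deposited RPKM, on recovered reads and on thinned libraries. No single gene called both in the main test and in an alternative turned its direction. The balance of higher and lower calls did turn in TUR and between accessions. In darkness it went to 3432 higher and 3528 lower in CYP with median-ratio scaling. The limma tests on RPKM computed from the counts also lacked TMM scaling, so test and scaling changed together there. At a 2-fold minimum the calls were 593 in TUR, 965 in CYP, 174 for the difference, 2057 between accessions in darkness and 2592 in light, and 351 in the overlap. At an adjusted p under 0.01 they were 1522 in TUR, 2326 in CYP, 122 for the difference and 943 in the overlap. These settings ask for more by construction. For the difference, limma gave 219 calls on log2(RPKM + 1) and 218 on log2(RPKM + 0.1), and the cause was not tested. On deposited RPKM the overlap was 1026, with 1944 calls in TUR and 2779 in CYP, and the cause was not tested. Accessions were not compared on deposited RPKM. Leaving out 1 library gave 1888 to 2963 calls in TUR and 164 to 451 for the difference, where fewer samples remain. The other total counts stayed within 1.5 times, but not all counts by direction. For the difference, the 64 calls above 0 became 129 with a replicate block, 124 with DESeq2, 26 to 112 with 1 library left out and 37 on log2(RPKM + 0.1). The 287 calls below 0 became 129 to 339 with 1 library left out, 163 on log2(RPKM + 5), 164 on log2(RPKM + 1) and 181 on log2(RPKM + 0.1). On deposited RPKM the rises in TUR were 865 and the falls in CYP 1448. DESeq2 called 2963, 3978 and 479 genes in TUR, in CYP and for the difference. Of 24 list calls, 13 held with an estimated correlation, and the cause was not tested. Over other settings the 331 named results had 5232 values, of which 366 were weaker, 5 stronger and 0 turned. With 1 library left out, 298 of 2322 were weaker and 2 stronger. Same-numbered libraries correlated from -0.106 to 0.182 within accessions in their deviations from group means, and from -0.353 to 0.079 between accessions. A pairing of samples by replicate number was thus neither shown nor excluded. With a replicate block the calls were 3123 in TUR, 4246 in CYP and 480 for the difference. Small differences between light responses may have been missed, since 23% of simulated 1.5-fold differences were recovered. The simulation varied neither depth nor replicate number and held no light response shared by the accessions.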

Other observations

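All tests described here were chosen only after the results were seen, except those of duplicate reads and of the nearly silent genes, whose limits were written before. For the nearly silent genes, the conditions that leave both tests undecided were not among those limits. By the limits alone both explanations of these genes would have passed. Grouping the tested genes by their description text gave 195 families of at least 10 genes, tested with camera over 975 tests, of which 0 were called with an estimated correlation. In TUR light, 26 of 189 pentatricopeptide repeat genes, which act on organelle RNA, rose and 1 fell (camera adjusted p = 0.00167, and adjusted p = 0.894 with an estimated correlation). Of 16 ketoacyl-CoA synthase genes, which lengthen fatty acids, 8 rose and 0 fell in TUR light (camera adjusted p = 0.00531, and adjusted p = 0.863 with an estimated correlation). For the difference between accessions 3 of them were lower and 0 higher (camera adjusted p = 1.91e-10, and adjusted p = 0.439 with an estimated correlation).

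Of 35 genes whose description names the pectin methylesterase inhibitor family, 14 fell and 0 rose in TUR (camera adjusted p = 0.000529) and 18 fell and 0 rose in CYP (camera adjusted p = 0.000123), both with adjusted p = 0.742 with an estimated correlation. They were grouped by that text alone, so which of them act as inhibitors was not examined. Of 12 minichromosome maintenance genes, whose products form the replicative helicase, 10 fell and 0 rose in CYP light (camera adjusted p = 3e-08, and adjusted p = 0.439 with an estimated correlation). In TUR light 3 of them fell and 0 rose (camera adjusted p = 0.055), and for the difference 6 were lower and 0 higher (camera adjusted p = 2.25e-07, and adjusted p = 0.439 with an estimated correlation).

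The deposited TUR RPKM held 29.8 to 38.4% of the reads in the TUR counts. The kept share of the densest genes was at most 0.301 of that of the sparsest, which argues against random drawing, and the kept share fell with read density (Spearman -0.873 across genes in the weakest library). Removal of duplicates stays open, since up to 12 genes exceeded 2 recovered reads per base, over the limit of 10. That limit was wrong, since reads trimmed to different lengths are not duplicates and reads can start outside a short model, and the highest recovered density was 4.08 against 85.81 counted. No biological explanation was tested.

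Of genes of at least 10 CPM in TUR and over 16-fold lower in CYP, all 43 read at 2.02% or more of the TUR level in CYP, while the choice of genes sets the upper end, and TUR library medians of at most 0.83% for the mirrored genes argue against exchange both ways. Among 101 genes of at least 2 CPM in TUR light, chosen likewise within light, AA32G00414 read at 0.84%. It had 3 reads where the median share would give 15.3 (Poisson test, adjusted p = 0.0168). In darkness 0 of 110 genes fell short, but only 44 of them had 10 or more reads at the median share. A shortfall in many of the others could not pass, so that 0 says little. TUR seeds or RNA in the CYP lots or libraries stay open, since AA32G00414 goes against a share common to all genes. Related models sharing reads also stay open, since 26 of the 43 genes have another model of the same Arabidopsis match, and with CYP dark replicate 3 left out, shares differed over both conditions and were not shown to differ within 1 (Friedman test over genes, which are not independent replicates, n = 43, p = 1.56e-08 over both, 0.12 in CYP light and 0.286 in CYP dark). The library left out differed most in its condition (median 6.31% against 2.93 and 2.89%), and as 1 library it decides nothing here.

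In all, 7 genes of at least 5 CPM in CYP had at most 3 reads in TUR, and 0% of such silent genes were silent in CYP. At a share of 2.02% a gene of 5 CPM in TUR would keep 6.36 reads in CYP, so this count says nothing of the reference. Of the 5 with another model of the same Arabidopsis match, 80% differed less than 2-fold once summed. In 4 of them other models outweighed the gene in the sum, so the sum decides nothing about reads taken by a related model, which stays open.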
